A study of Mus musculus with 2 samples.

How the data were processed

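The series measured gene expression in single cells of duodenal crypts, the pits of the small intestinal lining where its stem cells lie, from wild-type mice in 2 groups that the labels call NT and ES without spelling the letters out. Per the labels' protocols, crypts were released with 5 mM EDTA over 30 min on ice, passed through a 70 µm mesh, broken into single cells with TrypLE Express for 5 min, passed through a 40 µm mesh, and pooled from 5 animals in each group. Each group is therefore 1 library and there are no replicates. No p-value, standard error or count of changed genes can be given for the treatment.

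The authors deposited raw UMI counts (unique molecular identifiers, each taken as 1 captured RNA molecule) per gene and barcode, as 1 matrix that holds both libraries, with a list of barcodes and a list of genes. Per the file header the values are integers, and they were used as deposited, with no normalization by the authors. Cell Ranger 2.1.1 and the build mm10 are named in the submitters' processing notes. How barcodes were called as cells is not given in the sources used here. The labels name a droplet kit with 3' reads (Chromium V3), whereas the barcodes are 27 bases long, which is not the barcode length of that kit, so the capture chemistry behind the counts is not settled here.

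Each barcode ends in the number 1 or 2, and these numbers were taken to mark the 2 libraries. No label ties a number to NT or ES. Following the design fixed before the data were examined, each numbered library was given its own values, and no direction between NT and ES was drawn. All ratios below are those of library 2 to library 1 and compare these libraries, not the treatments. The rule for named genes had been written for a ratio of ES to NT and was used with library 2 to library 1 in its place.

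The matrix lists 31253 features, which came to 31205 gene symbols after the counts of 43 shared symbols were merged. A reference annotation, GENCODE M21 on the same mouse build, holds 99.5% of the feature identifiers and gave the coordinates. Cells with at least 500 genes and at most 25% of UMIs from mitochondrial genes were kept, which left 7784 of 12756 barcodes and removed 4972, or 39.0%. Putative doublets were sought in each library with scrublet as built into scanpy. It marked 12 cells of library 1 and 4 of library 2, 0.206% of the cells, which is too few for a caller that works, so doublets remain in the data. Removing these 16 cells left 7768 cells, 4045 in library 1 and 3723 in library 2.

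Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used with 15 neighbours, and Leiden clustering at resolution 1 with no integration of the libraries gave 19 clusters. Clusters took "-like" names from marker lists fixed before the data were examined. The scoring threshold for a name, a mean log2 enrichment of 0.25 with at least 3 detected markers, was lowered after a first, stricter value had left many clusters without a name. A cluster also stayed unnamed where markers of another class outnumbered its own among its top 10 genes by fold, or where none of its own was there. This left 7 unnamed clusters with 34.5% of the cells of library 1 and 38.7% of those of library 2. Of these clusters, 3 were shallow, with 17.3% and 9.51% of the cells.

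UMIs were summed per library and class, for classes with at least 50 cells in each library, and expressed as counts per 1000000 UMIs of the class (CPM). Genes with at least 100 UMIs over both libraries were measured. The ratio of CPM was given with the exact conditional 95% interval of a ratio of 2 Poisson counts. A gene was described as apart when its ratio was at least 1.5 in either direction and the interval excluded 1, which is a rule of size. Shares of cells carry exact Clopper-Pearson 95% intervals. All intervals, and the floor of 3 counts used where a library had no UMI, cover counting error only and not differences between animals.

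In total 36 gene lists, fixed before the data were examined, were summarised by the median log2 ratio over members with at least 20 UMIs. List members were called apart by the same size rule from 20 UMIs on, not 100. The simulated rates below cover only genes with at least 100 UMIs. Listed genes apart in opposite directions between classes were counted from 100 UMIs on. The list medians were placed among 10000 random lists of the same size matched on expression in 20 bins, and the percentile describes these libraries only. Of 609 listed symbols 606 were matched, H2afx through its newer name H2ax. Cell cycle phases were called from the S and G2M lists with each cell thinned to 2000 UMIs, which left out 779 cells of library 1 and 483 of library 2. The named genes were, by the bound of the interval nearest to 1, the 10 highest and 10 lowest in the stem-like class, 5 and 5 in the cycling progenitor-like and enterocyte-like classes, 3 and 3 elsewhere, up to 3 members of each list in the stem-like class, and all measured members of the stem and senescence lists. Ribosomal protein, mitochondrial and unnamed gene models were not named in the ranked part.

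The ratios were tested on simulated data with Poisson noise drawn from the real class sums. In the stem-like class, run on 8991 genes, the size rule took 28 of 67 genes changed 1.5-fold (41.8%), 66 of 67 changed 2-fold (98.5%), 66 of 66 changed 3-fold and 39 of 8792 unchanged genes (0.444%). In the lymphocyte-like class, run on 3454 genes, it took 52.2%, 94.0% and 98.5% at these sizes and 1.07% of unchanged genes. The simulation holds no spread between animals, so it says nothing about how often pools of untreated mice would differ. Alternatives fixed before the data were examined covered the cell filter, doublets, clustering resolution, number of variable genes, thinning, class assignment, centring of components per library, median-of-ratios and TMM scaling, removal of mitochondrial and ribosomal genes, minimum counts, the size rule, the weight of cells, free RNA and cells called G1. Some alternatives were chosen after seeing the data: leaving out the 5% of cells with the highest doublet scores, the largest stem-like cluster alone, and shallow clusters left out of the denominator. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.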

Results

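Single-cell counts from mouse duodenal crypts were deposited for 2 libraries, each a pool of 5 wild-type animals, and the title of the series names chronic stress and the ageing of intestinal stem cells as its subject. Library 1 held 6310 barcodes with 54316199 UMIs and a median of 4534.5 UMIs per barcode, and library 2 held 6446 barcodes with 54877667 UMIs and a median of 4996. The 4045 and 3723 cells kept had medians of 10845 and 11766 UMIs, 3440 and 3627 genes, and 10.1% and 9.19% mitochondrial UMIs. There were no replicates, and which library was NT and which was ES stayed open. Every comparison is therefore between numbered libraries, none has a test, and each interval covers counting error only.

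The first question was which cells the crypts held. Epithelial clusters, those with more Epcam than Ptprc, made up 93.0% of the kept cells in each library. Stem-like cells, led by Lgr5, a receptor of R-spondins that marks crypt base stem cells, and by Olfm4, a secreted glycoprotein of the same cells, were 12.2% of library 1 (95% interval 11.2 to 13.2, 492 cells) and 10.7% of library 2 (9.77 to 11.8, 400 cells). Enterocyte-like cells, the absorptive lineage, were 12.6% (11.6 to 13.6) and 7.31% (6.49 to 8.19), and goblet-like cells, which secrete mucus, were 12.5% (11.5 to 13.6) and 16.0% (14.9 to 17.3). Paneth-like cells, which secrete defensins at the crypt base, were 5.07% and 5.40%, and enteroendocrine-like cells, which secrete hormones, were 2.30% and 2.90%.

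Cycling progenitor-like cells were 12.9% and 10.6% of the libraries, T or intraepithelial lymphocyte-like cells 6.87% and 6.34%, and tuft-like cells, chemosensory cells marked by Dclk1, 1.09% and 1.99% (44 and 74 cells). The enterocyte-like class was made of different clusters in the libraries: cluster 8, led by Alpi, Slc13a1 and Reg1, held 373 and 64 cells, and cluster 9, led by Cyp3a11, Slc2a2 and Apoa1, held 136 and 208. Of the goblet-like cells, cluster 7, led by Clca1, Zg16 and Fcgbp, held 200 and 357, and cluster 16, led by Agr2, Creb3l1 and Atoh1, held 306 and 240. An unnamed cluster led by Reg3g and Reg3b, antimicrobial lectins of the epithelium, held 156 cells of library 1 and 474 of library 2, and another led by Gsdmc4 and Gsdmc2 held 180 and 386. The Reg3g cluster scored highest on the enterocyte list, at 0.825, above the 0.458 of cluster 8, which took the name. It stayed unnamed because a marker of another class, and none of its own, stood among its top genes. It made up 3.86% and 12.7% of the libraries, so the lower enterocyte-like share of library 2 depends on leaving it out. A cluster mostly of 1 library may reflect that library rather than a cell type. The stem-like share rested on how clusters fell: with the 16 putative doublets kept it was 23.6% and 16.9%, and with no cell filter 16.4% and 17.5%. It also leaves out unnamed clusters that scored highest on the stem list. A cluster led by Slfn9, Hells and Uhrf1 held 266 and 127 cells, and a cluster led by Knstrn, Ccnb2 and Cenpa held 96 and 99. Shallow unnamed clusters held 17.3% of library 1 and 9.51% of library 2, which lowers every other share unequally.

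**Figure D1:**
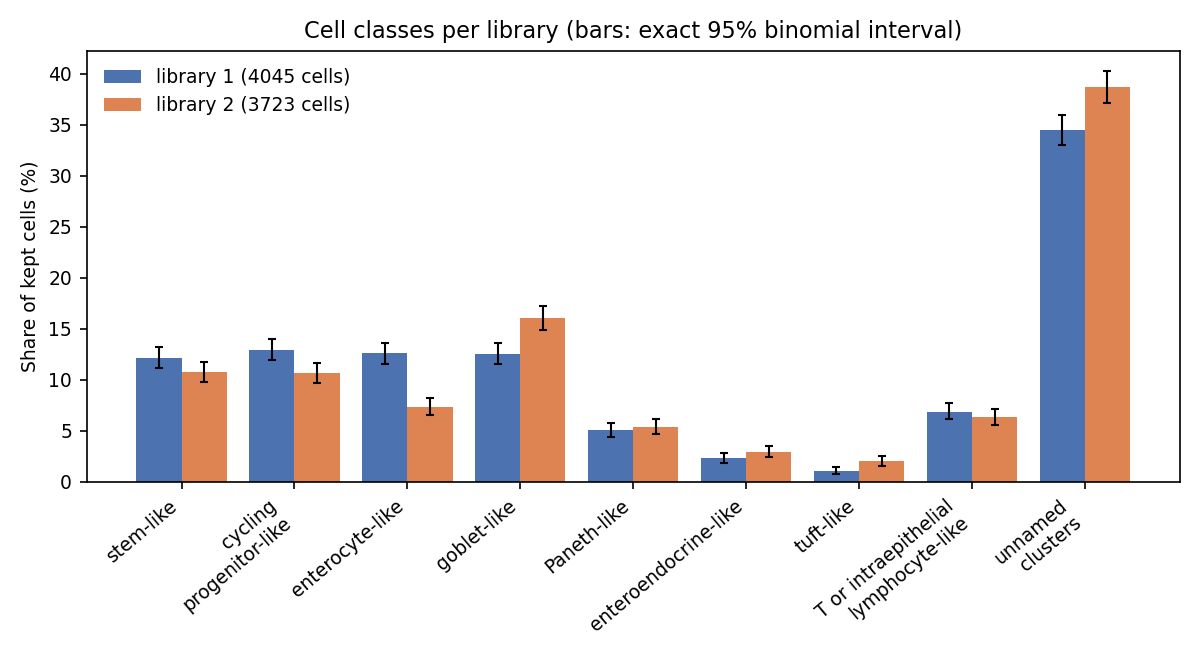
Share of kept cells in each class (%), with 1 bar per library and exact 95% binomial intervals for counting error. Enterocyte-like cells were 12.6% of library 1 and 7.31% of library 2, goblet-like cells 12.5% and 16.0%, and unnamed clusters 34.5% and 38.7%. The unnamed clusters include the cluster led by Reg3g, which scored highest on the enterocyte list and held 3.86% and 12.7%.

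Within the stem-like cells, the question was which genes stood apart between the libraries. Interferon-induced genes were higher in library 2: Oasl2, an antiviral protein of the oligoadenylate synthetase family, was at 28.8 CPM in library 1 and 113 in library 2, a ratio of 3.92 (95% interval 3.33 to 4.63). Genes of antigen presentation went the same way, with H2-Aa, a chain of MHC class II, at 28.9 and 91.1 CPM (3.15, 2.66 to 3.74) and Cd74, the class II invariant chain, at 200 and 451 CPM (2.26, 2.11 to 2.42). Immediate early genes, induced within minutes of a stimulus and many of them coding for transcription factors, were lower in library 2: Nr4a1 was at 80.8 and 30.7 CPM (0.380, 0.317 to 0.453) and Egr1 at 794 and 409 CPM (0.515, 0.490 to 0.541). Lgr5 was nearly level, at 197 and 190 CPM (0.962, 0.885 to 1.04).

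Of 8993 genes measured in the stem-like class, 161 were apart and higher in library 2 and 89 apart and lower, 2.78% of the genes together, and with a 2-fold rule 48 and 20 were. With each cell thinned to 2000 UMIs the counts were 57 and 61, without the excess of higher genes. The minimum of 100 UMIs was kept there, so genes with few UMIs dropped out. By the bound of the interval nearest to 1, the 10 that ranked highest in library 2 were Gip, Ifi44, Rtp4, Phf11d, H2-Q7, Oasl2, Oas1a, Irf7, Ftl1-ps1 and H2-Aa. Ifi44 was at 4.18 and 36.6 CPM (8.77, 5.89 to 13.5), Rtp4 at 5.97 and 47.4 CPM (7.95, 5.68 to 11.4) and Irf7, a transcription factor of the interferon response, at 5.37 and 21.9 CPM (4.09, 2.79 to 6.11). H2-Q7, Oas1a and the ferritin pseudogene Ftl1-ps1 have near-identical copies that could share their reads, so their ratios of 4.87, 3.89 and 3.74 are uncertain. Gip, the incretin hormone of enteroendocrine cells, was at 4.48 and 43.9 CPM (9.81, 6.69 to 14.9) in stem-like cells, and its ratio lay between 6.2 and 10.5 in each of the 8 classes. A like ratio in its source class and in classes that should lack it is that of background RNA, and Gip is read as background in every class but the enteroendocrine-like. The 10 that ranked lowest were Nr4a1, Atf3, Fosb, Hbegf, Nr4a2, Egr1, Csrnp1, Insm1, Ppp1r15a and Areg. Among them, Atf3 was at 137 and 55.1 CPM (0.403, 0.352 to 0.460), Fosb at 302 and 137 CPM (0.452, 0.415 to 0.492), and Hbegf and Areg, ligands of the EGF receptor, had ratios of 0.431 and 0.391. Insm1, a transcription factor of enteroendocrine cells, had a ratio of 0.366 at 16.3 and 5.95 CPM, and its direction turned with no cell filter, with a stricter one, at a lower clustering resolution and without the cells of highest doublet score.

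The genes lie as follows in the mouse build mm10 and its GENCODE annotation, all protein coding: Lgr5 (ENSMUSG00000020140) on chromosome 10 from 115450311 to 115587780, Olfm4 (ENSMUSG00000022026) on chromosome 14 from 79984081 to 80023139, and Oasl2 (ENSMUSG00000029561) on chromosome 5 from 114896936 to 114912234. H2-Aa (ENSMUSG00000036594) lies on chromosome 17 from 34282744 to 34287823 and Cdkn1a (ENSMUSG00000023067) on the same chromosome from 29090976 to 29100727. Nr4a1 (ENSMUSG00000023034) lies on chromosome 15 from 101254269 to 101274795, and Egr1 (ENSMUSG00000038418) on chromosome 18 from 34859823 to 34864984. Gip (ENSMUSG00000014351) lies on chromosome 11 from 96024545 to 96030831.

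**Figure D2:**
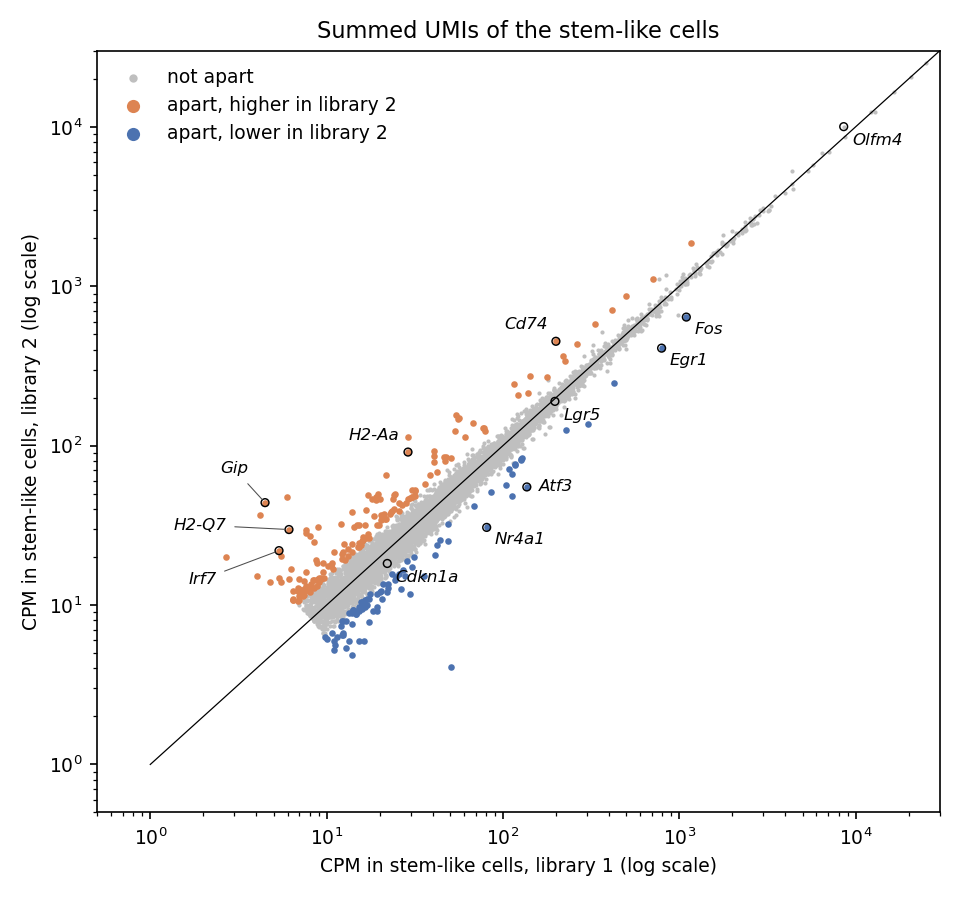
Summed expression of each gene with at least 100 UMIs over both libraries in the stem-like cells, in CPM on log scales, with library 1 on the horizontal axis, library 2 on the vertical axis and the line of equal values drawn, for genes seen in both libraries. Genes apart by the size rule are coloured, 161 higher and 89 lower in library 2. Lgr5 lies close to the line, Cd74 above it and Egr1 below it.

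All 23 members of the interferon list were higher in library 2 in stem-like cells, 20 of them apart, with a median log2 ratio of 1.60 at percentile 100 of matched random lists. The median was 0.81 when only members with at least 100 UMIs were counted and 0.82 in cells called G1. All 7 MHC class II members were apart and higher (median 1.25, percentile 100), and of the 10 MHC class I members all were higher and 7 apart (0.69, percentile 100), with B2m, the light chain of class I, at 714 and 1113 CPM (1.56, with bounds of 1.5 and 1.62), H2-K1 at 416 and 712 CPM (1.71) and H2-D1 at 334 and 583 CPM (1.75). The lymphocyte genes Ptprc, Cd3g and Gzma together were at 26.7 and 49.7 CPM in the stem-like cells and at 33215 CPM in the lymphocyte-like cells. An unnamed cluster of 5 and 23 cells, which scored highest on the B cell list, had H2-Aa and H2-Eb1 among its top genes. For the MHC class II genes of stem-like cells, background RNA was not separated from expression. All 15 immediate early members were lower in library 2, 10 of them apart, with a median of -0.78 at percentile 0. In cells called G1 the median was -0.26.

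Stem list genes helped to define the class, which limits how far their levels can differ within it. Of the list, 0 of 16 members were apart, 5 were higher and 11 lower, and the median of -0.015 lay at percentile 40.8. Olfm4 was at 8559 and 10024 CPM (1.17, 1.16 to 1.19), Ascl2, a transcription factor of stem cell fate, at 125 and 123 CPM (0.987, 0.890 to 1.09), and Slc12a2 at 2638 and 2449 CPM (0.928, 0.907 to 0.949). Smoc2 (0.996), Axin2 (0.991), Prom1 (0.997), Igfbp4 (0.981), Lrig1 (1.05), Rgmb (1.08) and Cdca7 (0.952) had intervals that included 1. So did Bmi1, at 40.7 and 33.9 CPM (0.831, 0.685 to 1.01), and Tert, the catalytic subunit of telomerase, at 4.33 and 4.28 CPM (0.989, 0.546 to 1.77). Msi1 was at 76.8 and 96.3 CPM (1.25, 1.11 to 1.42), Hopx at 224 and 253 CPM (1.13, 1.05 to 1.22) and Sox9 at 285 and 265 CPM (0.928, 0.866 to 0.995).

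Of the senescence list, 14 of 16 members were measured in the stem-like cells, 6 higher and 8 lower in library 2, and the median of -0.074 lay at percentile 13.4. Gdf15, a stress-induced cytokine, was the 1 member apart, at 9.10 and 3.53 CPM (0.388, 0.219 to 0.659). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 22.1 and 18.2 CPM (0.826, 0.633 to 1.07). Cdkn2a, which encodes the inhibitor p16, had no UMI in either library, where a count of 0 in 492 and 400 cells allows shares of cells with a UMI of up to 0.747% and 0.918% at the 95% level. Ccng1, a p53 target, was at 146 and 110 CPM (0.755, 0.681 to 0.838), Trp53 at 270 and 248 CPM (0.917, 0.854 to 0.985), and H2ax, a histone phosphorylated at DNA breaks, at 120 and 157 CPM (1.31, 1.19 to 1.44). Intervals included 1 for Bax (0.895), Mdm2 (1.05), Lmnb1 (0.983), Glb1 (1.15), Trp53inp1 (0.853), Plk2 (0.807), Sesn2 (1.03), Cdkn2d (1.04) and Cdkn2b (1.71). Of the secretory phenotype list only 5 members could be measured (median -0.45, percentile 0.255), with Areg (0.391) and Cxcl10 (18 and 4 UMIs) apart and lower. Ccl20 was at 16.6 and 12.1 CPM (0.730) and Ccl5 at 27.9 and 33.9 CPM (1.21). This median was above 0 with a stricter cell filter and in cells called G1.

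Stress response lists other than immediate early genes had medians between -0.18 and 0.11 in stem-like cells. The heat shock list had a median of -0.12 (percentile 0.685, 10 of 11 lower), with Hsph1 at 148 and 110 CPM (0.749) and Hspa1b, the 1 member apart, at 12.4 and 6.70 CPM (0.541), a direction that was lost with the stricter cell filter. The glucocorticoid response list had a median of -0.18 (percentile 0.570), with Dusp1 (0.543), Errfi1 (0.550) and Sgk1 (0.551) apart and lower and Cebpd (1.64) and Mt2 (1.57) apart and higher. Dusp1 is also a member of the immediate early list, so these lists are not independent. The unfolded protein response list had a median of -0.018 (percentile 42.1), with Sdf2l1 at a ratio of 1.41, Atf4 at 0.859 and Dnajb9 at 0.799. Oxidative stress (median 0.063, percentile 98.1, below 0 with no cell filter and with the stricter one; Gpx2 1.14, Txn1 1.11), DNA damage repair (0.11, percentile 98.9; Msh6 1.22, Parp1 0.859) and apoptosis (-0.084, percentile 10.0; Mcl1 0.825, Bcl2l1 1.37) had no member apart. Of the catecholamine receptors, fewer than 3 were measured, and Adra2a was at 85.5 and 74.6 CPM (0.873, 0.766 to 0.993).

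Absorption genes were higher in library 2 in stem-like cells: the sugar and amino acid transport list had a median of 0.63 (percentile 100, 6 of 14 apart), with the brush border peptidase Anpep at 142 and 275 CPM (1.94, 1.79 to 2.11) and the disaccharidase Sis at 30.6 and 47.4 CPM (1.55). Lipid absorption had a median of 0.20 (percentile 99.9), with Apoa1 at 40.9 and 85.9 CPM (2.1, 1.81 to 2.45) and Apoc3 at 17.4 and 26.2 CPM (1.5). The antimicrobial list had a median of 0.27 (percentile 100, 16 of 17 higher), with the Paneth cell ribonuclease Ang4 at 67.7 and 139 CPM (2.05), Nos2 at 14.3 and 30.7 CPM (2.14) and the defensin Defa21, whose family members share sequence, at 53.7 and 123 CPM (2.30). Most transcripts of other cell types were also higher in library 2 in lymphocyte-like cells, which should lack them: 7 of the 8 examined had intervals above 1, with Gip at a ratio of 7.35 (2.93 to 23.7), the goblet cell mucin Muc2 at 3.16 (2.02 to 5.12), Itln1 at 1.39 and Lyz1 at 1.26. In lymphocyte-like cells Defa24 was at 1509 and 2129 CPM (1.41, 1.31 to 1.52), Apoa1 at 30.3 and 79.1 CPM (2.61, 1.60 to 4.43) and Fabp1 at 37.2 and 67.1 CPM (1.8, 1.13 to 2.95), while Olfm4 was not higher (0.922, 0.724 to 1.18). Fabp1 was lower in library 2 in goblet-like (0.712), cycling progenitor-like (0.767) and enteroendocrine-like cells (0.430). In Paneth-like cells, its source, Defa24 had a ratio of 1.01. For the absorption and antimicrobial genes of stem-like cells, background RNA was not separated from expression.

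Fatty acid oxidation and ketogenesis had a median of -0.12 (percentile 0.260, 14 of 18 lower) in stem-like cells, with Cpt1a at 221 and 192 CPM (0.870) and Hadha at 403 and 352 CPM (0.872). Nuclear genes of oxidative phosphorylation (median 0.060, percentile 99.9, below 0 with no cell filter and with the stricter one; Cox4i1 1.09, Ndufa4 1.10), mitochondrially encoded genes (-0.0083, percentile 43.0), glycolysis (0.074, percentile 97.2; Ldha 1.05) and cholesterol synthesis (0.11, percentile 97.6; Sqle 1.39) lay near 0. Of the Notch pathway (0.049, percentile 70.8), Hes1, a repressor that blocks secretory fate, was at 389 and 294 CPM (0.755, 0.709 to 0.804), and of the Wnt targets (-0.030, percentile 29.8) Myc was at 150 and 168 CPM (1.12) and Tcf7 at 31.2 and 22.5 CPM (0.722). The regeneration and YAP list (0.12, percentile 85.4) held Ccn1 at 117 and 76.8 CPM (0.657), and the EGF, BMP and niche list (-0.016, percentile 46.6) held Id1 at 117 and 76.1 CPM (0.649). Enterocyte factors (-0.049, percentile 20.9; Klf4 0.513), mTORC1 and autophagy (0.00074, percentile 53.5; Ddit4 0.773), tight junction and adhesion (0.045, percentile 91.7; Epcam 0.930), iron and duodenal transport (0.0036, percentile 55.8; Heph 1.46), histone and chromatin (-0.030, percentile 33.8; Hmgb1 0.883) and ribosomal protein genes (-0.023, percentile 21.2) also lay near 0. So did secretory lineage factors (0.015, percentile 56.5; Sox4 0.918), of which Atoh1 (34 and 45 UMIs, 1.65), Spdef (7 and 28 UMIs, 4.99) and Foxa3 (1.51) were apart and higher, beside Muc2 at 1.88 in stem-like and 3.16 in lymphocyte-like cells. Klf4, given above with the enterocyte factors, also belongs to the immediate early list. Members that the rule for named genes did not pick and that were named after their values were seen, because they stood apart, are Cxcl10, Sgk1, Mt2, Atoh1 and Spdef.

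Whether stem-like cells differed in cell cycle was read from phase calls and from transcripts. With each cell thinned to 2000 UMIs, 19.6% of the stem-like cells of library 1 were called G1, 39.8% S and 40.6% G2M, and in library 2 these shares were 20.9%, 40.8% and 38.3%, with overlapping intervals for each phase. Unthinned, G1 was 16.5% and 19.8%. The phase shares leave out the unnamed cluster led by Slfn9, Hells and Uhrf1, which scored highest on the stem list (0.454). Its top genes include members of the S phase list, and it held 266 cells of library 1 and 127 of library 2. The likeness of the phase shares therefore holds for the named class only. The S phase list had a median of 0.059 (percentile 99.2; Rad51ap1 1.39, Gmnn 1.19) and the G2M list of -0.026 (percentile 22.8; Top2a 1.19, Cdk1 1.22, Cdc20 0.823), with 0 members apart in both. The S phase median turned below 0 under several alternatives. Lgr5 was seen in 30.6% (26.5 to 35.0) and 27% (22.7 to 31.7) of thinned stem-like cells, against 0.488% and 0% of lymphocyte-like cells (median depths 2425 and 3220 UMIs, 12222 and 12761 in stem-like cells), and in 63.4% and 63.5% unthinned. Olfm4 was seen in 99.2% and 98.2% of thinned stem-like cells and in 24.9% and 29.0% of lymphocyte-like cells. Cdkn1a was seen in 3.54% (2.08 to 5.61) and 4.59% (2.74 to 7.16) of thinned stem-like cells and in 1.95% (0.534 to 4.92) and 5.18% (2.51 to 9.32) of lymphocyte-like cells. These intervals overlap. Lymphocyte-like cells may express the gene themselves, so background and expression cannot be told apart at this level. Mki67 was seen in 45.4% and 41.3% of the thinned stem-like cells, against 11.4% and 5.91% of enterocyte-like and 13.7% and 30.1% of lymphocyte-like cells.

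Cycling progenitor-like cells showed the same gene groups: of 9247 genes measured, 230 were apart and higher in library 2 and 107 apart and lower. The highest ranked were Ifi44 (1.13 and 36.9 CPM), Gip, Rtp4, Phf11d and Oasl2 (24.0 and 103 CPM, 4.31), and the lowest Nr4a1 (73.1 and 16.0 CPM, 0.219), Fosb (295 and 73.5 CPM, 0.249), Atf3 (181 and 48.6 CPM, 0.269), Fam71a and Dusp1 (114 and 38.3 CPM, 0.338). The interferon median was 1.57 and the immediate early median -1.09, with 14 of 15 members apart and lower. Enterocyte-like cells, with 564 and 679 genes apart of 7973, had an interferon median of 2.76, led by Ifit1 (5.65 and 162 CPM, 28.7), Ifi44, Usp18, Ifit3 and Trim30a, and an immediate early median of -0.98, with Nr4a1 (0.177), Hbegf (0.335), Klf10, Fosb and Egr2 ranked lowest. Library 1 filled this class mostly from cluster 8 and library 2 from cluster 9. Within cluster 9 alone the interferon median was 2.19 and within cluster 8 it was 1.0. The balance of the counts depended on the rule and the cluster: with a 2-fold rule they were 242 and 111 in the class, 38 and 68 in cluster 8 and 81 and 16 in cluster 9, and with the 1.5-fold rule 259 and 176 in cluster 8 and 242 and 100 in cluster 9. Within cluster 9 Ifit1 had a ratio of 10.8. Goblet-like cells had 321 and 317 of 8934 genes apart, with Ifi27l2a (1.51 and 32.1 CPM, 21.3), Slfn5 and Ly6a highest and Rbp7, Otc and Reg1 (264 and 120 CPM, 0.455) lowest, and an immediate early median of -0.10 at percentile 20.1. Within cluster 7 these counts were 188 and 50, Ifi27l2a had a ratio of 9.72 and the immediate early median was -0.23, and within cluster 16 the counts were 304 and 125 and the median -0.36, both medians at percentile 0.

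Paneth-like cells of library 1 held more stem cell transcripts than those of library 2: the stem list had a median of -1.21, with 11 of 15 members apart and lower, the Wnt target list -1.08, and Olfm4 was at 1803 and 625 CPM (0.347, 0.328 to 0.367). The genes ranked lowest were Igfbp4 (71.9 and 17.4 CPM, 0.242), Sfrp5 (0.203), a secreted Wnt inhibitor, and Olfm4, and the highest Gip, Oasl2 (16.0 and 76.4 CPM, 4.78) and Clca1. The median log2 ratio over all 4006 genes measured there was -0.10, of which 178 were apart and higher and 355 apart and lower. Enteroendocrine-like cells of library 2 had fewer proliferation transcripts, with S and G2M medians of -1.31 and -1.36, Top2a at 298 and 76.8 CPM (0.258, 0.197 to 0.334) and Cdk1 at 85.3 and 10.7 CPM (0.125), beside Pclaf among the lowest. Their Gip was at 1560 and 13031 CPM (8.35, 7.93 to 8.80), Fabp5 at 81.6 and 557 CPM (6.83) and Sphkap at 16.9 and 107 CPM (6.32), and 568 and 408 of 4234 genes were apart. Other transcripts differed there too: the mitochondrially encoded list summed to 87238 and 59429 CPM, ribosomal protein genes to 30223 and 18088 CPM, and the stem list to 3351 and 2015 CPM. These are averages of 93 and 108 cells, so the mix of cells within the class is part of each value.

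T or intraepithelial lymphocyte-like cells of library 2 had more proliferation transcripts, with S and G2M medians of 0.89 and 0.76, Mki67, a marker of cycling cells, at 208 and 533 CPM (2.57, 2.13 to 3.10) and Top2a at 253 and 665 CPM (2.63, 2.22 to 3.12). The highest ranked genes were Ly6a (16.5 and 257 CPM, 15.6), Ifit1 (8.26 and 123 CPM, 14.9) and Ifi27l2a (53.7 and 495 CPM, 9.22). The lowest were Klrh1 (0.146), Tyrobp, an adaptor of natural killer receptors (927 and 191 CPM, 0.206), and Klrd1, the receptor CD94 (999 and 256 CPM, 0.256). In total 230 and 215 of 3437 genes were apart, and the interferon median was 0.72. The class was made of different cells in the libraries: at clustering resolution 2 it split into a cluster led by Cd7, Gzma and Trgc1, a chain of the gamma-delta T cell receptor, with 241 and 86 cells, and one led by Trbc2, a chain of the alpha-beta receptor, with 37 and 150. All these ratios therefore include the mix of cells.

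**Figure D3:**
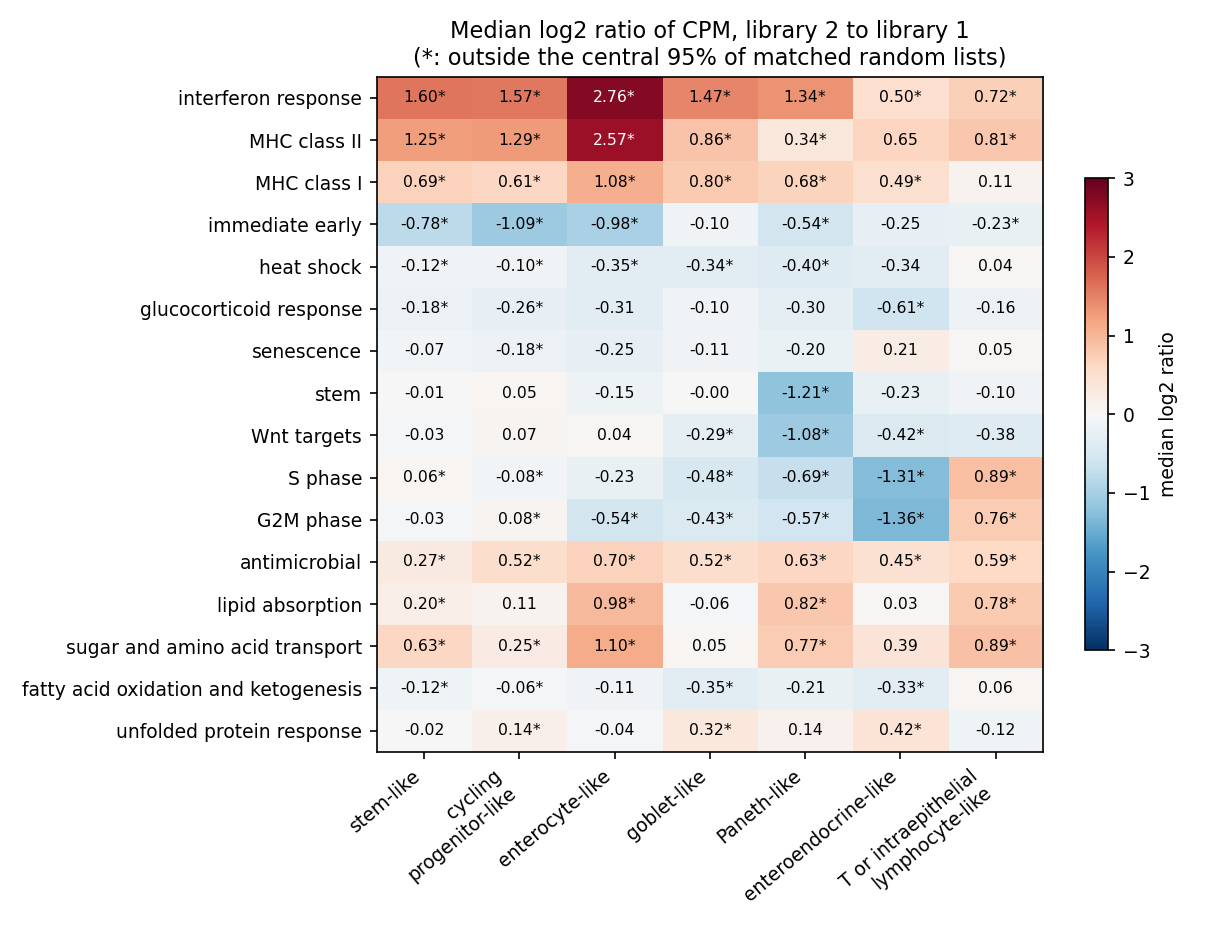
Median log2 ratio of CPM, library 2 to library 1, of 16 gene lists (vertical axis) in the 7 classes with at least 50 cells in each library (horizontal axis), with the value printed in each cell, colour from -3 to 3, and a star outside the central 95% of matched random lists. Interferon medians lay between 0.50 in enteroendocrine-like and 2.76 in enterocyte-like cells, and the stem list stood lowest in Paneth-like cells at -1.21.

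**Figure D4:**
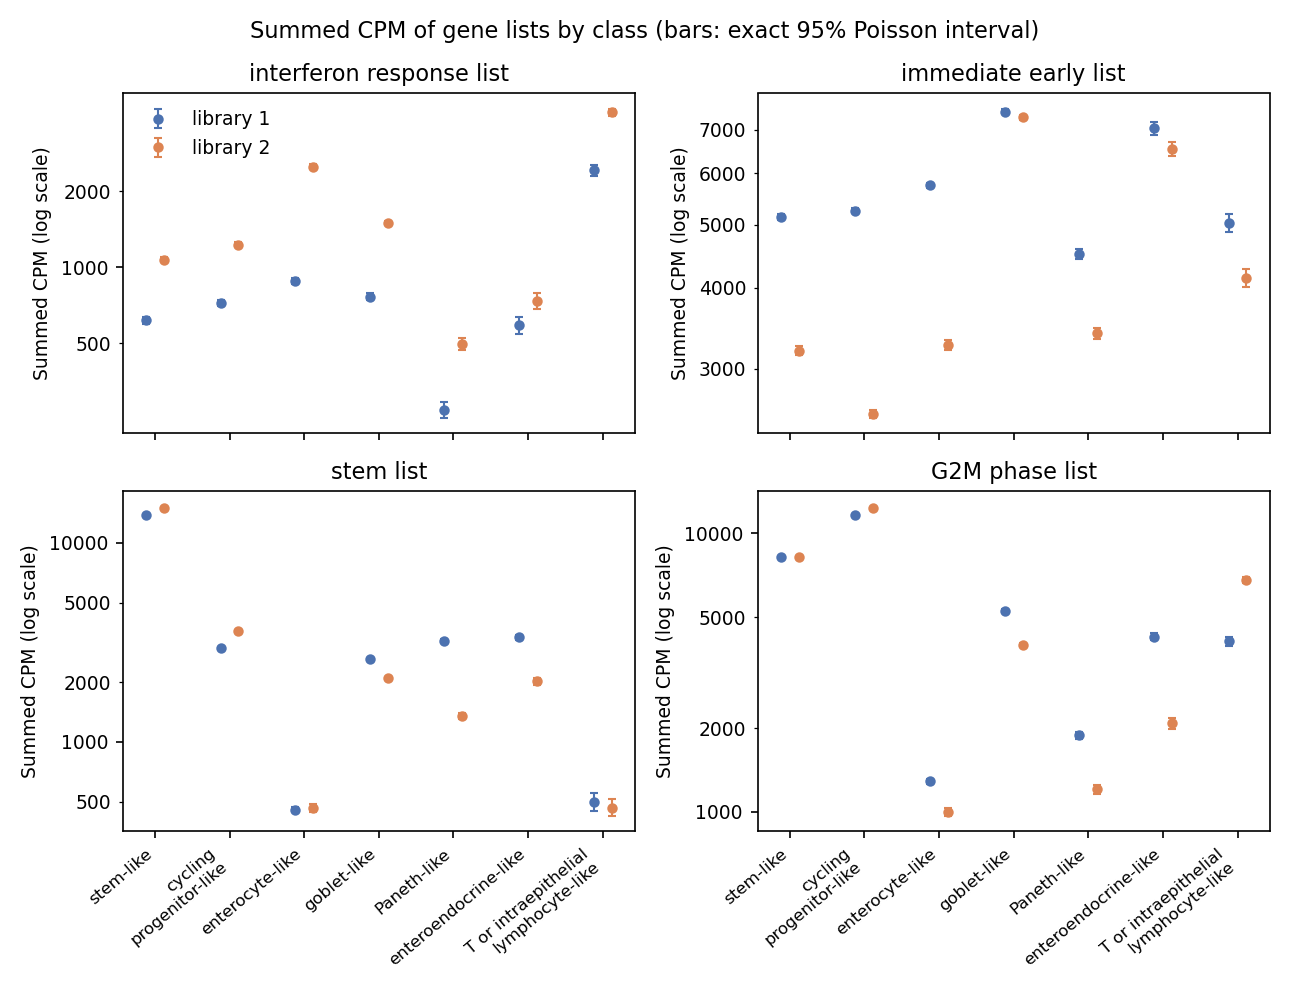
Summed CPM (log scale) of the interferon, immediate early, stem and G2M lists in each of 7 classes, with 1 point per library and exact 95% Poisson intervals for counting error. The interferon sum in stem-like cells was 615 in library 1 and 1073 in library 2, and the immediate early sum 5146 and 3199.

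Summed over all epithelial cells, which mixes composition and level, 605 of 11738 genes were apart and higher in library 2 and 191 apart and lower. Ifi44 (3.98 and 56.0 CPM, 14.1), Ifit1 (2.27 and 29.5 CPM, 13.0) and Nts, which encodes the gut peptide neurotensin (4 and 107 UMIs), ranked highest, and Gdf15 (6.19 and 1.98 CPM, 0.320), Fam71a and Nrros lowest. The interferon median was 1.70 (21 of 23 apart) and the immediate early median -0.61. The secretory lineage factors stood at 0.59 (percentile 100) and the S and G2M lists at -0.40 and -0.30 (percentile 0), beside medians near 0 for all these in stem-like cells. The stem list stood at -0.17 (percentile 0.060, 15 of 16 lower) and the senescence list at -0.13 (percentile 1.17). The secretory phenotype list stood at 0.25 (percentile 95.6, 5 of 8 higher), against -0.45 in stem-like cells. Xist, expressed from the inactive X of females, was at 0.331 and 0.273 CPM over all deposited barcodes, while the Y-linked genes Ddx3y (48.8 and 52.6 CPM), Eif2s3y (53.3 and 70.3 CPM), Kdm5d (16.2 and 23.6 CPM) and Uty (17.0 and 21.6 CPM) were expressed in both. In the stem-like cells the list of Y-linked genes and Xist had a median of 0.21 (percentile 98.6).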

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

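The test of free RNA for the interferon genes was written only after the result was seen, as were a second reading of the depth test and a tighter reading of the handling test. The other tests were written before the values they measure were seen. No test here bears on NT or ES, since no label ties a library to either, and the treatment, the animals of each pool and the preparation of each library all remain open for every pattern.

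The barcodes left out by the cell filter, which entered the comparisons of classes only when no filter was applied, held interferon transcripts. In library 1 their level was 797 CPM (95% interval 775 to 821) over 2253 barcodes, and in library 2 it was 1399 CPM (1374 to 1424) over 2719 barcodes. Both levels lie above what a count of 0 allows, 0.506 and 0.360 CPM, a limit that so many barcodes of the same tissue would pass in any case, so it supports no conclusion. In stem-like cells the same list summed to 615 and 1073 CPM.

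Some genes stood apart in opposite directions in different cell classes. Of the listed genes, 40 were apart and higher in library 2 in at least 1 class and apart and lower in another, and 22 of these belong to the cell cycle lists. All 22 were higher in lymphocyte-like cells: Mki67 had a ratio of 2.57 there, 0.402 in enteroendocrine-like and 0.643 in Paneth-like cells, and Top2a had ratios of 2.63, 0.258 and 0.583. Of 45 cycle genes measured in lymphocyte-like cells, 28 were apart and higher and 0 apart and lower. Klf4, an epithelial differentiation factor, also belongs to the immediate early list. It was higher in enterocyte-like cells (1.93) and lower in stem-like (0.513) and cycling progenitor-like cells (0.576). Enterocyte-like cells came from different clusters in the libraries, and within clusters 8 and 9 of that class its ratios were 0.901 and 1.31, neither of them apart. The mix of clusters is thus part of the directions read in enterocyte-like cells, as it is in lymphocyte-like cells, which split at resolution 2 into clusters of 241 and 86 and of 37 and 150 cells. This reading follows from sizes in single libraries, and the difference between classes was not tested.

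Interferon genes were higher in library 2 in each of the 7 classes compared. Free RNA from 1 pool was expected to add a like amount to every class, in CPM or per cell. The added CPM ran from 148 (75.8 to 220) in enteroendocrine-like to 1686 (1508 to 1858) in lymphocyte-like cells, a ratio of 11.4. In UMIs per cell it ran from -0.35 (-1.06 to 0.358) in enteroendocrine-like to 21.9 (21.1 to 22.7) in enterocyte-like cells. Without the lymphocyte-like and enterocyte-like classes, whose mix of clusters differed, the cycling progenitor-like cells still had 506 CPM (475 to 536) and 8.3 UMIs per cell (7.74 to 8.85). These values argue against free RNA as the whole cause, with a limit. Defa24, a Paneth cell transcript, did not rise evenly either, from 1763 to 2093 CPM in stem-like and from 1446 to 2257 in enterocyte-like cells. In enteroendocrine-like cells it went from 1849 to 2618 CPM and in cycling progenitor-like cells from 1531 to 2141. Lymphocytes joined to stem-like cells would have to make up 11.2% of their RNA, while Ptprc, Cd3g and Gzma were higher by only 0.0691% of their lymphocyte level (upper bound 0.0903%), which argues against them. Unequal depth predicted a median nearer to 0 once all cells were thinned. The thinned median was 1.11 against 0.81 for the same 14 members, and the bound set beforehand, a shift within 0.2, was not met. By the later reading the median was larger in each of 10 thinnings (0.87 to 1.29). Cells were thinned after the classes were set, which changes a ratio of summed CPM on average only through the weight of cells. The test therefore decides nothing about depth, whose medians in stem-like cells were 12222 and 12761 UMIs. A real interferon response in the animals of library 2 may therefore remain, as a hypothesis, beside depth and differences between pools and preparations.

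Immediate early genes were higher in library 1. A different mix of stem-like clusters is argued against, since the median was -0.79 in the cluster nearest to 0 and -0.85 in the other. Dissociation of crypts can itself induce these genes, and handling of the whole preparation was expected to put every class, lymphocytes included, below 0: all 7 medians were, from -1.09 in cycling progenitor-like to -0.10 in goblet-like cells. Under the tighter reading, which asks each class to lie outside the matched random lists, goblet-like (percentile 20.1) and enteroendocrine-like cells (percentile 5.41) missed, although the medians within goblet-like clusters 7 and 16 were -0.23 and -0.36, both at percentile 0. Handling therefore stays open and could account for the pattern, and a response in the animals cannot be told apart from it with 1 preparation per group.

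Stem cell genes were higher in the Paneth-like cells of library 1 (list median -1.21), and Olfm4 was also lower in library 2 in enteroendocrine-like (0.326), tuft-like (0.476) and goblet-like cells (0.583, but 1.27 and 0.75 within clusters 7 and 16) and higher in cycling progenitor-like (1.38), stem-like (1.17) and enterocyte-like cells (1.12). Free RNA as the whole cause is argued against, since Olfm4 had a ratio of 0.922 (0.724 to 1.18) in lymphocyte-like cells against an upper bound of 0.367 in Paneth-like cells. Paneth and stem cells captured together would carry more UMIs: the Paneth-like cells of library 1 with more than 0.2% stem gene UMIs, 39.0% of them (32.3 to 46.1), had a median of 15586 UMIs against 13568 in the others, and the interval of the difference, -6361 to 6278, decides nothing. Their doublet score (0.0790 against 0.0237) and Mki67 level (190 against 53.1 CPM) were higher, and their summed Lyz1, Defa24 and Itln1 lower (216907 against 307288 CPM). Such cells of library 2, 11.4% of its Paneth-like cells, went the same way (0.0761, 169 CPM, and 225255 against 277560 CPM). Their median was 4301 UMIs against 12518.5 in the others, and the interval of the difference, -11058 to 897, decides nothing either. Near the 0.2% cut lay 53 of 205 and 50 of 201 Paneth-like cells, so the shares above it depend on the cut. Joint capture, which may differ between preparations, and stem cell transcripts within Paneth cells cannot be told apart here.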

How the results depend on the processing

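Of the alternatives, leaving out the 5% of cells with the highest doublet scores, taking the largest stem-like cluster alone and leaving shallow clusters out of the denominator were chosen only after the data were seen. Values are those of stem-like cells, list values are median log2 ratios of library 2 to library 1, and where a value moved or turned the cause was not tested unless it is named. No paired analysis was possible because the labels give replicate 1 in each group and nothing that links an animal of one pool to an animal of the other.

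Under each alternative that gave a value, the interferon median stayed above 0 (0.81 to 1.81, 12 alternatives), as did the MHC class II median (1.16 to 1.55), and the immediate early median stayed below 0 (-0.94 to -0.26). The senescence median stayed below 0 (-0.17 to -0.041), whereas the stem list lay on both sides of 0 (-0.13 to 0.21). The stem-like share ran from 10.1% to 23.6% in library 1 and from 9.48% to 17.5% in library 2, and was lower in library 2 except with no cell filter. Of the values that answer a comparison, 71 stayed within their bounds and 55 moved beyond them; of the other values 2244 stayed, 625 moved and 19 turned.

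With no cell filter the shares were 16.4% and 17.5%, the cells called S or G2M 73.9% in library 2, and the medians -0.94 for immediate early and 1.37 for interferon genes. S phase (-0.0094), oxidative phosphorylation (-0.086), oxidative stress (-0.067) and Insm1 (0.86) turned. With the stricter filter the share in library 1 was 18.9% and its cells in S or G2M 85.4%, with medians of 0.21 for the stem list, -0.57 for immediate early, 1.71 for interferon and 1.55 for MHC class II genes. Insm1 (1.22), Hspa1b (0.020), S phase (-0.046), the senescence secretory phenotype (0.019), oxidative phosphorylation (-0.061), cholesterol synthesis (-0.00056) and oxidative stress (-0.027) turned.

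With the putative doublets kept the shares were 23.6% and 16.9%, the stem median -0.061 and the immediate early median -0.89. Leaving out the highest doublet scores gave shares of 20.1% and 13.2%, a senescence median of -0.15, an interferon median of 1.09, and Insm1 turned (0.43). At resolution 0.5 the share in library 1 was 10.1%, the cells in S or G2M 74.5% and 72.8%, and the medians -0.13 for the stem list, -0.90 for immediate early, 1.37 for interferon and 1.16 for MHC class II genes; S phase (-0.013) and Insm1 (1.02) turned. At resolution 2 the share in library 2 was 9.48%, the interferon median 1.81 and the MHC class II median 1.39, and S phase turned (-0.039). The shares were 20.9% and 15.8% with cells thinned before clustering, 18.9% and 15.5% with classes given cell by cell, and 14.7% and 11.9% without shallow clusters, where a smaller denominator raises them by construction.

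The number of genes apart moved with the minimum by construction: 305 higher and 167 lower at 20 UMIs, 35 and 19 at 500 UMIs, and 48 and 20 with a 2-fold rule. With each cell thinned to 2000 UMIs 57 were higher and 61 lower, so the excess of higher genes was lost. The minimum of 100 UMIs was kept there, so genes with few UMIs dropped out. With the mean over cells 140 were lower, and the medians were 1.44 for interferon and 1.16 for MHC class II genes. With at least 100 UMIs per member the interferon median was 0.81, since members with few UMIs and high ratios drop out.

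In stem-like cells called G1 the medians were -0.062 for the stem list, -0.17 for senescence, -0.26 for immediate early, 0.82 for interferon and 1.35 for MHC class II genes. S phase (-0.12), DNA damage repair (-0.013) and the senescence secretory phenotype (0.15) turned, as did the immediate early median of cycling progenitor-like cells (0.52), where few cells were called G1. The largest stem-like cluster alone gave -0.14 for senescence, -0.85 for immediate early, 1.17 for interferon and 1.16 for MHC class II genes. Depth limits which genes were measured, 8993 in stem-like and 3437 in lymphocyte-like cells. A change of 1.5-fold was taken in 41.8% and 52.2% of the simulated genes of these classes, since the rule itself asks for an observed ratio of 1.5, so differences near that size can be missed.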

Other observations

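The values here were read from the tables with no test, and all were chosen after they were seen, except those of tuft-like cells, whose genes follow the rule for named genes. Genes of senescence and stress signals differed in level between the named cell classes, with CPM pooled over both libraries. Among these classes Cdkn1a, the gene of p21, was highest in enteroendocrine-like cells at 829 CPM (95% interval 789 to 870; 641 in library 1 and 1042 in library 2), followed by enterocyte-like cells at 173 CPM, and stood at 20.4 CPM in stem-like cells and 20.2 CPM in lymphocyte-like cells. Cdkn2b, which encodes the inhibitor p15, was at 87.6 CPM in enterocyte-like cells and at 3.15 CPM in stem-like cells, and at 115 and 128 CPM in the unnamed cluster led by Reg3g. Adra2a, an adrenergic receptor, was at 80.6 CPM in stem-like cells and at 42.5 CPM in goblet-like cells. Adrb1, another adrenergic receptor, was at 106 CPM in lymphocyte-like cells and had no UMI in stem-like cells.

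The unnamed cluster led by Reg3g and Reg3b, 3.86% of library 1 and 12.7% of library 2, had Ifi44 at 12.7 and 85.3 CPM and an interferon median log2 ratio of 1.18, but Reg3b was lower in library 2, at 7476 and 3680 CPM (0.492, 0.483 to 0.501). In the unnamed cluster led by Gsdmc4 and Gsdmc2, Reg3b was at 2997 and 1080 CPM (0.360, 0.348 to 0.373). Tuft-like cells, with 44 cells in library 1 and thus too few for the comparisons, had Oasl2 at 30.8 and 299 CPM, Ifi27l2b at 49.0 and 247 CPM, and Reg3g at 401 and 1525 CPM. Their lowest ranked genes were Fos, at 969 and 260 CPM, Fosb, at 274 and 70.5 CPM, and the potassium channel subunit Kcne3, at 142 and 49.4 CPM.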
